A study of Mus musculus with 18 samples.

How the data were processed

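RNA was measured in the livers of 18 mice, 6 in each of 3 groups. Per the labels' protocols, 45 male C57BL/6 mice aged 6 weeks entered the experiment, 15 per group. Control mice had olive oil injected into the peritoneum and water by gavage, the CCl4 group had carbon tetrachloride (CCl4) injected 2 times per week and water by gavage, and the third group had the same CCl4 injections and daily PTH by gavage. CCl4 is a solvent that liver cytochrome P450 enzymes turn into a reactive radical, and repeated doses injure hepatocytes and scar the liver. PTH and PZH are both used in the labels for Pien Tze Huang, a traditional Chinese medicine, and were taken as one preparation. The third group is called CCl4_PTH, and libraries carry the numbers given in their labels. Tissue was taken in week 22. Whether the piece of liver held tumour, and how long after the last CCl4 injection it was taken, is not given in the sources used here.

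Per the labels' protocols, RNA was extracted with TRIzol, ribosomal RNA was removed, and libraries from a NEBNext kit were read as 150-base pairs on an Illumina HiSeq instrument. The submitters' processing notes name FastQC 0.11.9, cutadapt 4.2, HISAT2 2.2.1, StringTie 2.1.5, Bowtie2 2.5.1 and the mouse build GRCm38, with no role or order. Which tool counted reads, with which annotation, filters and strand setting, is not given in the sources used here. The deposited table holds estimated counts per gene, taken as such from its identifiers and values, as whole numbers not scaled to depth, for 54752 genes in 18 libraries. Because the use of strand is not stated, genes that overlap another gene on either strand, and members of families of near-identical genes such as the Mup and Cyp genes, may hold reads of their neighbours or copies. The small RNA and circular RNA libraries of the same study were not analysed here.

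Counts were rounded to whole numbers, which changed none of the deposited values. Of the 54752 genes, 18164 had 0 counts in all 18 libraries, and 54723 identifiers matched the GENCODE M21 annotation of GRCm38, which gave gene classes and coordinates, while 29 did not match. The expression filter of edgeR (filterByExpr, minimum count 10) kept 21840 genes, of which 14942 were protein-coding and 2763 were long noncoding RNAs. Where 94 symbols occurred more than once, identifiers kept the genes apart. Counts were scaled with TMM factors and given as CPM, the counts scaled to a common library size by edgeR. Total counts ran from 67229863 to 118877267 per library. The 357 loci counted as ribosomal RNA (nuclear and mitochondrial ribosomal RNA genes, and Gm42418, whose exon overlaps one of them) took 30.6% to 55.8% of the counts, which left between 35.6 M and 79.7 M counts for other genes. No pair of libraries within a group agreed within sampling noise (smallest chi-square per gene 68.2 over 45 pairs), so all 18 libraries counted as separate replicates.

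All 3 comparisons came from one fit of edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, 3 groups, no block), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A gene called higher or lower passed that threshold. Log2 fold changes are given with an approximate standard error (SE), the fold change divided by the square root of F. For a gene with 0 counts in a whole group, the fold is a lower bound against a floor of 3 counts over that group, which covers counting error only. Each of 44 gene lists (1038 symbols, 3 of them not found) was described by its called members, over all genes and adjusted over the list alone, and 43 lists with at least 5 measured members were tested with camera (limma 3.58.1, preset correlation 0.01) on voom log2 values, adjusted over the lists of a comparison. Camera asks whether a list moved relative to the other genes. With a correlation between genes estimated per list, 0 of the 43 lists passed in any comparison, while 13, 10 and 8 lists had an unadjusted p under 0.05, and fry, which asks whether a list moved on balance at all, called 37, 24 and 21 lists (CCl4 against control, CCl4_PTH against CCl4, CCl4_PTH against control). A list score is the mean log2 CPM of the list's measured members. Single values per library were compared with two-sided exact permutation tests.

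The groups, the comparisons, the tests, the lists and the rule for naming genes were set before the data were examined. The rule took, for CCl4 against control and for CCl4_PTH against CCl4, the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold with at least 1 CPM on average, a symbol that is a name, and medians 1.5 times apart, then 3 long noncoding RNAs per direction, and the 2 members with the smallest p of each of the 10 lists with the smallest camera p. CCl4_PTH against control took 3 genes per direction, and 11 genes (Cyp2e1, Col1a1, Acta2, Timp1, Tgfb1, Afp, Gpc3, H19, Cyp7a1, Mki67 and Alb) were followed in each comparison. Some genes the rule took are not reported here. List members named outside this rule were chosen after their values were seen. Both comparisons with the CCl4 group share its libraries, so the return towards control was computed again with the CCl4 libraries parted 3 and 3 between the comparisons, in 20 splits, and in 10 simulated data sets per setting.

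The pipeline was tested on simulated counts for the 21840 genes with 200 genes changed. The test for CCl4 against control called 20.9%, 53.7% and 69.7% of genes changed 1.5-fold, 2-fold and 4-fold, with 3 false calls. For CCl4_PTH against CCl4 these shares were 22.4%, 46.3% and 81.8% with 6 false calls, and for CCl4_PTH against control 29.9%, 49.3% and 81.8% with 2. The simulation thus missed most 1.5-fold, many 2-fold and some 4-fold changes. With only 200 genes changed, its adjusted threshold was stricter than in the real data, where 47.4% of genes were called in CCl4 against control. These shares therefore cannot be carried over to the real comparisons. Camera recovered the raised list, cholesterol synthesis, in each of the 3 comparisons and called 1, 0 and 0 other lists. The simulated genes were drawn independently, while the correlation estimated for this list in CCl4 against control was 0.640. The simulation therefore cannot tell how often camera with its preset correlation calls correlated lists falsely. A simulated return with a slope of −0.5 was recovered as −0.40 over 4 splits. Alternatives were other scalings, no expression filter, DESeq2 1.42.0, limma voom with sample quality weights, only the 2 groups compared, the label numbers as a block, a fold beyond 2, and each library left out in turn. Removal of the ribosomal RNA loci, the ribosomal RNA share as a covariate, library sizes without composition factors, upper quartile scaling for the lists, and leaving out control 1 with CCl4_PTH 1 were chosen after seeing the data.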

Results

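Long RNA of liver tissue, after removal of ribosomal RNA, was counted gene by gene in 6 control mice, 6 mice given CCl4, and 6 mice given CCl4 and PTH. Total counts were 82.2 M ± 3.14 (SD, n = 6) in control, 76.7 M ± 6.49 (SD, n = 6) in CCl4 and 103 M ± 16.1 (SD, n = 6) in CCl4_PTH libraries. CCl4_PTH libraries were deeper than CCl4 libraries (exact permutation test, two-sided, p = 0.0108, Benjamini-Hochberg adjusted p = 0.0649 over 6 tests) and than control libraries (exact permutation p = 0.0216, adjusted p = 0.0649), and neither difference passed the adjustment. Ribosomal RNA loci took 46.3% ± 8.17, 41.9% ± 4.47 and 37.7% ± 5.87 of the counts (SD, n = 6, in the order control, CCl4, CCl4_PTH), with exact permutation p from 0.0714 to 0.266 and adjusted p from 0.143 to 0.266 for the 3 pairs of groups. Genes with at least 1 count numbered 24866 ± 440 in control, 27386 ± 833 in CCl4 and 27877 ± 720 in CCl4_PTH libraries (SD, n = 6). Mitochondrial messenger RNA took 1.11% ± 0.114, 1.04% ± 0.212 and 1.25% ± 0.242 of the counts in the same order (SD, n = 6). Ddx3y, a Y-linked gene, had 29.8 to 51.5 CPM and Xist 0.0611 to 0.800 CPM over the 18 libraries.

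The first principal component of log2 CPM held 44.5% of the variance and had group means of −106 ± 7.35 in control, 78.8 ± 29.9 in CCl4 and 27.7 ± 23.1 in CCl4_PTH libraries (SD, n = 6). The second component held 7.65%, and on it CCl4_PTH 1 lay at −43.4 while the other 5 CCl4_PTH libraries lay between 32.3 and 55.1. CCl4_PTH 1 also had an acute phase score of 8.95 against 5.46 to 6.03 in the other 5, a neutrophil marker score of 3.59 against −0.271 to 1.05, and a pericentral score of 4.69 against 6.23 to 6.44. It stayed in its group, and values without it stand beside some of the results it moved.

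The first comparison asked what repeated CCl4 did to the liver at week 22. Of the gene lists, 24 of 25 collagen and matrix genes, 22 of 24 macrophage markers and 30 of 35 cell cycle genes rose, while 23 of 30 pericentral hepatocyte genes and 29 of 32 male-biased genes fell. These 5 lists passed camera with its preset correlation and did not pass with an estimated one (adjusted p from 0.124 to 0.196 with an estimated correlation). Col1a1, the main chain of type I collagen (chromosome 11, 94936224 to 94953042), rose 26.2-fold, from 5.33 ± 2.33 to 140 ± 39.6 CPM (SD, n = 6). Gpnmb, a glycoprotein of lipid-associated macrophages (chromosome 6, 49036546 to 49070929), rose 141-fold, from 0.522 ± 0.190 to 73.5 ± 16.7 CPM (SD, n = 6). Slc1a2, a glutamate transporter of hepatocytes around the central vein (chromosome 2, 102658659 to 102790784, with an antisense gene overlapping its exons), fell 279-fold, from 242 ± 28.6 to 0.874 ± 0.772 CPM (SD, n = 6). Cyp2e1, the P450 enzyme that turns CCl4 into its reactive radical (chromosome 7, 140763739 to 140774987), fell 17.3-fold, from 4524 ± 1144 to 261 ± 208 CPM (SD, n = 6).

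Of the 25 measured collagen and matrix genes, 24 rose after CCl4 (24 adjusted over the list alone) and 1 did not pass. The median was 2.30 (camera adjusted p = 2.79e-15, adjusted p = 0.124 with an estimated correlation). Fbn1 (2.63 ± 0.18, with an antisense gene over its exons) and Lum (3.57 ± 0.24), both components of the fibrous matrix, had the smallest p of the list (log2 fold change ± SE, n = 6 per group, as in the values that follow). Col1a1 rose by 4.71 ± 0.42 on the log2 scale (edgeR adjusted p = 2.06e-07). Of 21 matrix remodelling genes, 19 rose (20 adjusted over the list alone). The median was 2.37 (camera adjusted p = 1.2e-07, adjusted p = 0.163 with an estimated correlation). Examples were the gelatinase Mmp2 (3.63 ± 0.22) and the procollagen protease Adamts2 (2.01 ± 0.17). Timp1, an inhibitor of matrix proteases, had 4 counts in all controls together and 3.66 ± 2.48 CPM after CCl4 (SD, n = 6, edgeR adjusted p = 5.35e-05). Of 22 stellate cell and myofibroblast markers, 11 rose and 1 fell (11 and 1 adjusted over the list alone). The median was 0.60 (camera adjusted p = 0.00545, adjusted p = 0.357 with an estimated correlation). Acta2, the smooth muscle actin of activated stellate cells, did not pass (0.47 ± 0.54, edgeR adjusted p = 0.502). Of 20 genes of TGF-beta signalling, 12 rose and 2 fell (13 and 2 adjusted over the list alone). The median was 1.04 (camera adjusted p = 0.000506, adjusted p = 0.163 with an estimated correlation), and Tgfb1 itself rose by 1.49 ± 0.20 (edgeR adjusted p = 1.08e-05).

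Of 24 markers of monocyte-derived and lipid-associated macrophages, 22 rose after CCl4 (22 adjusted over the list alone). The median was 3.70 (camera adjusted p = 1.99e-11, adjusted p = 0.139 with an estimated correlation). Gpnmb (7.14 ± 0.27) and the lipoprotein lipase Lpl (3.36 ± 0.20) had the smallest p of the list. Of 20 Kupffer cell markers, 13 rose and 1 fell (13 and 1 adjusted over the list alone). The median was 1.32 (camera adjusted p = 0.00443, adjusted p = 0.438 with an estimated correlation). Of 19 neutrophil markers, 18 rose (18 adjusted over the list alone). The median was 4.93 (camera adjusted p = 0.000747, adjusted p = 0.408 with an estimated correlation, and 0.0527 with library sizes only). Of 31 T and NK cell markers, 24 rose (26 adjusted over the list alone). The median was 2.5 (camera adjusted p = 0.000377, adjusted p = 0.438 with an estimated correlation, and 0.18 with library sizes only). Of 35 cytokine and chemokine genes, 31 rose and 1 fell (31 and 1 adjusted over the list alone). The median was 3.05 (camera adjusted p = 7.19e-08, adjusted p = 0.265 with an estimated correlation). The chemokine Cx3cl1 (3.47 ± 0.31) and the adhesion molecule Vcam1 (2.87 ± 0.31, with an antisense gene over its exons) had the smallest p of that list. Of 33 interferon-stimulated genes, 24 rose (25 adjusted over the list alone). The median was 0.95 (camera adjusted p = 1.18e-05, adjusted p = 0.408 with an estimated correlation). Of 24 acute phase genes, 11 rose and 2 fell (11 and 2 adjusted over the list alone). The median was 1.10 (camera adjusted p = 0.0394, adjusted p = 0.601 with an estimated correlation). This call ended without CCl4 2 (0.0606), without CCl4 5 (0.0637) and with library sizes only (0.166).

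Of 35 cell cycle genes, 30 rose after CCl4 (31 adjusted over the list alone). The median was 2.28 (camera adjusted p = 5.37e-10, adjusted p = 0.124 with an estimated correlation). Mki67, a marker of dividing cells, rose by 3.16 ± 0.18 (edgeR adjusted p = 7.55e-10) and the mitotic motor Cenpe by 3.43 ± 0.22. Of 23 liver cancer and oncofetal genes, 16 rose (17 higher and 1 lower adjusted over the list alone). The median was 2.40 (camera adjusted p = 1.18e-05, adjusted p = 0.118 with an estimated correlation). Gpc3, a fetal liver proteoglycan, rose by 2.85 ± 0.42 (edgeR adjusted p = 2.64e-05), the fetal plasma protein Afp by 0.95 ± 0.24 (edgeR adjusted p = 0.00318, 3.61 ± 1.62 against 1.86 ± 0.299 CPM) and the imprinted noncoding RNA H19 by 3.13 ± 0.94 (edgeR adjusted p = 0.0102, with other genes over its exons). H19 stood at 0.492 CPM in control 8 and at 0 to 0.176 CPM in the other controls. It had 3.37 CPM in CCl4 2 and 0.258 to 1.63 CPM in the other CCl4 libraries. Of 19 cholangiocyte and ductular genes, 16 rose and 1 fell (16 and 1 adjusted over the list alone). The median was 2.23 (camera adjusted p = 1.74e-05, adjusted p = 0.257 with an estimated correlation). Of 22 p53 targets and senescence genes, 15 rose and 1 fell (15 and 1 adjusted over the list alone). The median was 0.82 (camera adjusted p = 9.73e-05, adjusted p = 0.124 with an estimated correlation). Of 30 immediate early genes, 20 rose and 1 fell (20 and 1 adjusted over the list alone). The median was 1.45 (camera adjusted p = 3.47e-05, adjusted p = 0.268 with an estimated correlation). Of 28 genes of the unfolded protein and integrated stress response, 16 rose and 1 fell (16 and 1 adjusted over the list alone). The median was 0.50 (camera adjusted p = 0.000808, adjusted p = 0.408 with an estimated correlation). Of 26 NRF2 targets, 12 rose and 7 fell (13 and 7 adjusted over the list alone). The list did not pass (median 0.66, camera adjusted p = 0.159).

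Of 30 pericentral hepatocyte genes, 23 fell after CCl4 and 2 rose (23 and 2 adjusted over the list alone). The median was −1.75 (camera adjusted p = 9.13e-10, adjusted p = 0.196 with an estimated correlation). Examples were Slc1a2 (−8.12 ± 0.50) and the ornithine aminotransferase Oat (−4.69 ± 0.29). Cyp2e1 fell by 4.12 ± 0.43 on the log2 scale (edgeR adjusted p = 6.89e-07). Of 25 periportal hepatocyte genes, 4 rose and 6 fell (4 and 6 adjusted over the list alone). The list did not pass (median −0.17, which is 0.32 with library sizes only, camera adjusted p = 0.297). Of 32 male-biased liver genes, 29 fell (30 adjusted over the list alone). The median was −3.14 (camera adjusted p = 2.79e-15, adjusted p = 0.124 with an estimated correlation). Examples were the organic anion transporter Slco1a1 (−5.78 ± 0.31), Susd4 (−7.28 ± 0.47) and the steroid dehydrogenase Hsd3b5, which had 26 counts in all CCl4 libraries together and 88.1 ± 38.6 CPM in control (SD, n = 6). Of 27 female-biased genes, 8 rose and 6 fell (9 and 7 adjusted over the list alone). As a list they did not pass (median 0.36, camera adjusted p = 0.865). Mup12 (−10.02 ± 0.98) and Mup17 (−8.19 ± 1.24), which make urinary pheromone-binding proteins, fell and belong to a family of near-identical genes, so the member behind their counts is uncertain.

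Of 28 genes of P450 drug metabolism, 16 fell after CCl4 and 1 rose (16 and 2 adjusted over the list alone). The median was −0.90 (camera adjusted p = 4.85e-06, adjusted p = 0.268 with an estimated correlation). Of 20 bile acid synthesis genes, 15 fell (16 adjusted over the list alone). The median was −1.06 (camera adjusted p = 3.33e-08, adjusted p = 0.163 with an estimated correlation). Examples were the oxysterol hydroxylase Cyp7b1 (−3.53 ± 0.39) and Hsd3b7 (−1.15 ± 0.14, with other genes over its exons). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass (0.30 ± 0.67, edgeR adjusted p = 0.744). Of 19 bile transport genes, 14 fell and 2 rose (14 and 2 adjusted over the list alone). The median was −1.20 (camera adjusted p = 8.13e-07, adjusted p = 0.139 with an estimated correlation), and the sterol transporter Abcg8 fell by 2.76 ± 0.20 on the log2 scale, with an antisense gene over its exons. Of 34 genes of fatty acid oxidation, 26 fell and 2 rose (27 and 3 adjusted over the list alone). The median was −0.94 (camera adjusted p = 2.33e-07, adjusted p = 0.268 with an estimated correlation). An example was the peroxisomal enzyme Acaa1a (−1.58 ± 0.18), with an antisense gene over its exons. The fatty acid oxidation score of control 1 was 5.44, inside the 5.43 to 6.12 of the CCl4 libraries. Control 8 had 6.42 and the other controls 6.89 to 7.22, so the controls differed widely among themselves. Of 22 lipogenesis genes, 15 fell and 2 rose (15 and 2 adjusted over the list alone). The median was −1.06 (camera adjusted p = 0.002, adjusted p = 0.408 with an estimated correlation). Controls 1 and 8 had lipogenesis scores of 6.53 and 7.03, against 5.30 to 5.51 in the other controls and 4.71 to 5.41 in CCl4 libraries. The size of this fall therefore rested largely on these controls. Of 25 cholesterol synthesis genes, 10 fell (10 adjusted over the list alone). The median was −0.57 (camera adjusted p = 0.00255, adjusted p = 0.478 with an estimated correlation). Here too controls 1 and 8 were highest, with scores of 5.58 and 6.07. The other controls had 4.26 to 5.31 and the CCl4 libraries 4.34 to 5.03, ranges that overlap.

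Of 28 genes of gluconeogenesis, amino acid breakdown and the urea cycle, 11 fell after CCl4 (11 adjusted over the list alone). The median was −0.44, which is 0.11 with library sizes only (camera adjusted p = 0.000353, adjusted p = 0.408 with an estimated correlation). Of 35 secreted hepatocyte proteins, 20 fell and 2 rose (20 and 2 adjusted over the list alone). The median was −0.58 (camera adjusted p = 2.39e-05, adjusted p = 0.398 with an estimated correlation). Alb, the gene of serum albumin, did not pass (−0.54 ± 0.25, edgeR adjusted p = 0.0878), and passed in DESeq2 (0.0234), in voom with quality weights (0.0194), without CCl4 5 (0.0449) and without CCl4 8 (0.0314). Of 21 sinusoidal endothelial markers, 8 rose and 2 fell (8 and 2 adjusted over the list alone). As a list they did not pass (median 0.10, camera adjusted p = 0.272, and 0.0279 with library sizes only). Of 21 markers of vascular and capillarised endothelium, 11 rose and 1 fell (11 and 1 adjusted over the list alone). The median was 0.92 (camera adjusted p = 0.000864, adjusted p = 0.124 with an estimated correlation).

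The largest changes after CCl4 by the naming rule also held genes outside these groups. Sprr1a, Inava and Shc2 had 0 counts in control and were at least 830-fold, 427-fold and 414-fold higher. Mmp7 (10.01 ± 1.22, 4 counts in control), a matrix protease, and the fibrillin gene Fbn2 (8.26 ± 0.59) rose, where Inava, Shc2, Mmp7 and Fbn2 have antisense genes over their exons. Mup-ps16, Olfr542-ps1 and the noncoding Gm13775 had 0 counts after CCl4 and were at least 915-fold, 552-fold and 2428-fold lower, where Mup-ps16 and Gm13775 overlap other genes in sense. Cfd, a complement protease, fell by 8.67 ± 1.10 on the log2 scale to 4 counts after CCl4. Among long noncoding RNAs, Gm36161 (5.59 ± 0.71, antisense to another gene), AI506816 (3.92 ± 0.23) and Gm12840 (3.57 ± 0.73) rose, and Gm35696 (−4.51 ± 0.71) and Hectd2os (−4.10 ± 0.83, antisense to another gene) fell.

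**Figure D1:**
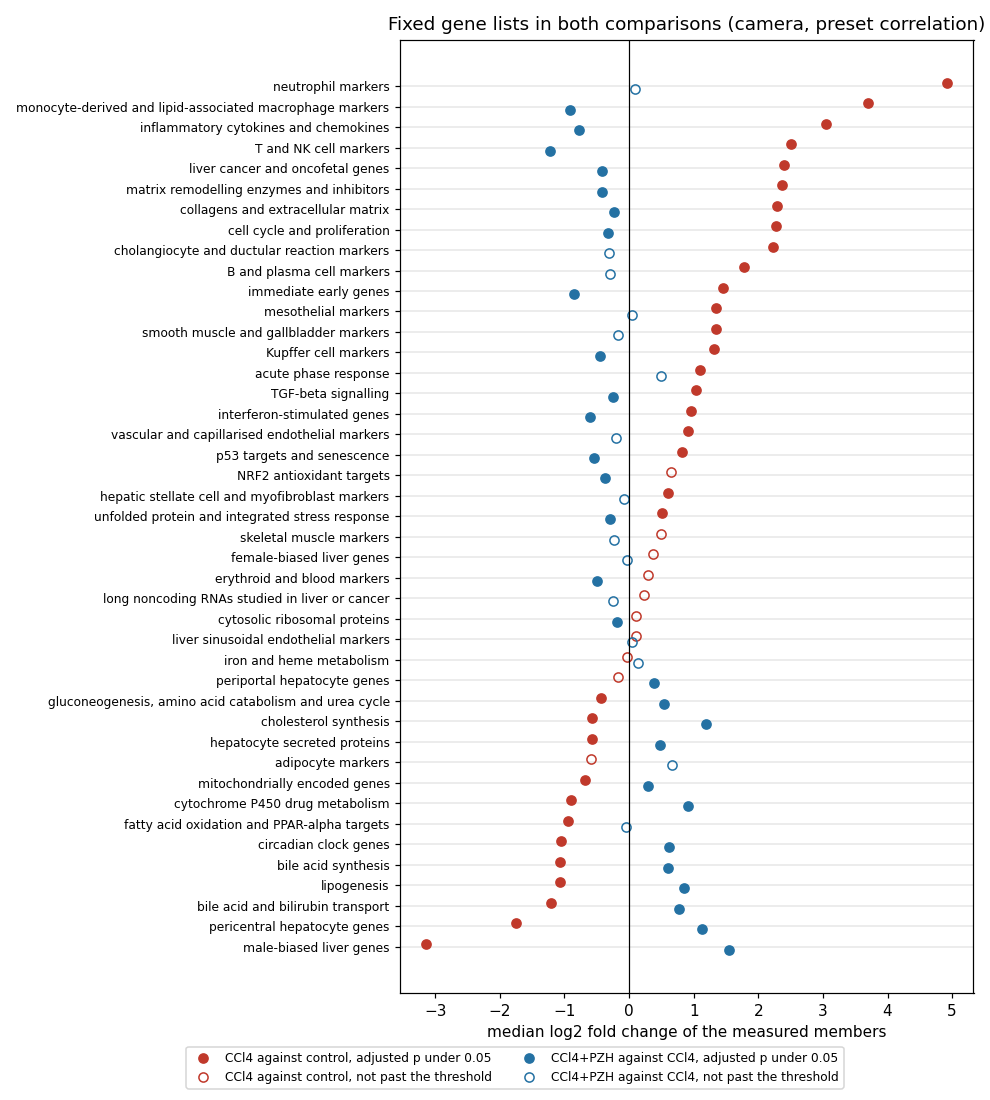
Median log2 fold change of the measured members of 43 gene lists in CCl4 against control (red) and CCl4_PTH against CCl4 (blue, drawn as CCl4+PZH), comparisons that share the CCl4 libraries, filled where camera passed with its preset correlation (0 passed with an estimated one). Pericentral genes stand at −1.75 and 1.14 and collagen genes at 2.30 and −0.24, and library sizes only turns the sign of the gluconeogenesis, periportal and iron lists in the first and of the neutrophil, sinusoidal and mesothelial lists in the second.

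In CCl4 against control, 5735 genes were higher and 4627 lower in the CCl4 group, 47.4% of the 21840 tested (edgeR quasi-likelihood, Benjamini-Hochberg), of which 3797 and 1418 passed with a change beyond 2-fold. Protein-coding genes made up 4648 and 3739 of these calls and long noncoding RNAs 471 and 386. With library sizes only, the median of all genes moved from 0.05 to 0.63 and the higher share of calls from 55.3% to 91.4%, so the balance of higher and lower genes rests on the scaling.

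The second comparison asked what PTH changed in livers that also had CCl4. With PTH, 20 of 25 cholesterol synthesis genes, 16 of 30 pericentral genes and 17 of 32 male-biased genes were higher, 11 of 24 macrophage markers and 12 of 30 immediate early genes were lower, and 24 of 25 collagen genes did not pass. These 6 lists passed camera with its preset correlation and did not pass with an estimated one (adjusted p from 0.206 to 0.492 with an estimated correlation). Slc1a2 rose 105-fold, from 0.874 ± 0.772 to 91.5 ± 32.3 CPM, and Cyp2e1 rose 7.03-fold, from 261 ± 208 to 1834 ± 499 CPM (SD, n = 6). Insig1, a sterol sensor of the cholesterol pathway (chromosome 5, 28071363 to 28078662), rose 3.16-fold, from 57.3 ± 16.5 to 181 ± 35.6 CPM (SD, n = 6). Atf3, a stress-induced transcription factor (chromosome 1, 191170296 to 191218039), fell 6.35-fold, from 14.6 ± 5.04 to 2.29 ± 0.658 CPM (SD, n = 6). Col1a1 did not pass, with 123 ± 77.6 against 140 ± 39.6 CPM (SD, n = 6, log2 fold change −0.19, edgeR adjusted p = 0.795). CCl4_PTH 1 held 268 CPM of Col1a1, and without it the log2 fold change was −0.55 (edgeR adjusted p = 0.253).

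Of 25 cholesterol synthesis genes, 20 rose with PTH (24 adjusted over the list alone) and 5 did not pass. The median was 1.19 (camera adjusted p = 3.15e-17, adjusted p = 0.206 with an estimated correlation). Among those that rose were Insig1 (1.66 ± 0.25) and the pathway enzymes Idi1 (1.98 ± 0.43) and Hmgcs1 (1.58 ± 0.31). Of 30 pericentral genes, 16 rose (24 higher and 2 lower adjusted over the list alone). The median was 1.14 (camera adjusted p = 1.36e-11, adjusted p = 0.206 with an estimated correlation). Examples were Slc1a2 (6.72 ± 0.47), Oat (2.82 ± 0.27) and the glutamine synthetase Glul (2.22 ± 0.23). Cyp2e1 rose by 2.81 ± 0.41 (edgeR adjusted p = 0.000551). Of 25 periportal genes, Aldh4a1, Igf1 and Pigr rose (5 adjusted over the list alone) and 22 did not pass. The median was 0.39 (camera adjusted p = 0.033, adjusted p = 0.507 with an estimated correlation). The periportal call ended without CCl4 2 (0.136), CCl4 4 (0.102), CCl4 7 (0.0621), CCl4_PTH 1 (0.0954), CCl4_PTH 6 (0.0687) or CCl4_PTH 7 (0.0755). Of 32 male-biased genes, 17 rose (22 higher and 1 lower adjusted over the list alone). The median was 1.55 (camera adjusted p = 7.7e-11, adjusted p = 0.206 with an estimated correlation). Examples were Slco1a1 (1.91 ± 0.27) and Cyp4a12b (2.87 ± 0.34). Of 27 female-biased genes, Cyp2g1 and Cyp3a41b rose (1 adjusted over the list alone), and the list did not pass. Its median was −0.03, its mean 0.55 and its test upward (camera adjusted p = 0.991).

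Of 28 P450 genes, 9 rose with PTH (16 higher and 1 lower adjusted over the list alone). The median was 0.92 (camera adjusted p = 8.38e-08, adjusted p = 0.257 with an estimated correlation), and Cyp2j5 rose by 1.06 ± 0.16. Of 20 bile acid synthesis genes, 9 rose (11 adjusted over the list alone). The median was 0.60 (camera adjusted p = 9.65e-08, adjusted p = 0.206 with an estimated correlation). Examples were the sterol carrier Scp2 (0.95 ± 0.15) and the bile acid ligase Slc27a5 (1.12 ± 0.19), while Cyp7a1 did not pass (0.54 ± 0.67, edgeR adjusted p = 0.669). Of 19 bile transport genes, 10 rose and 1 fell (12 and 1 adjusted over the list alone). The median was 0.77 (camera adjusted p = 1.68e-07, adjusted p = 0.206 with an estimated correlation). Examples were the sterol transporters Abcg8 (1.73 ± 0.19) and Abcg5 (1.43 ± 0.18), whose exons overlap antisense genes. Of 22 lipogenesis genes, 8 rose (13 higher and 1 lower adjusted over the list alone). The median was 0.84 (camera adjusted p = 1.17e-05, adjusted p = 0.291 with an estimated correlation). Examples were Srebf1 (1.96 ± 0.42) and Fasn (2.16 ± 0.62). Of 34 fatty acid oxidation genes, 2 rose and 2 fell (5 and 4 adjusted over the list alone), and the list did not pass. Its median was −0.05 and its mean −0.23, while its test was upward (camera adjusted p = 0.994). Of 28 genes of gluconeogenesis, amino acid breakdown and the urea cycle, 6 rose (11 adjusted over the list alone). The median was 0.53 (camera adjusted p = 9.65e-08, adjusted p = 0.291 with an estimated correlation), and Fah rose by 0.70 ± 0.18 (edgeR adjusted p = 0.0165, and 0.055 with only the 2 groups compared). Of 35 secreted proteins, 7 rose (16 adjusted over the list alone). The median was 0.48 (camera adjusted p = 3.01e-07, adjusted p = 0.291 with an estimated correlation). Examples were the coagulation factor F11 (1.60 ± 0.14) and Serpina3k (1.77 ± 0.29, overlapping another gene in sense), while Alb did not pass (0.08 ± 0.25, edgeR adjusted p = 0.883).

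Of 24 macrophage markers, 11 fell with PTH (14 adjusted over the list alone). The median was −0.92 (camera adjusted p = 5.14e-09, adjusted p = 0.206 with an estimated correlation). Examples were the monocyte chemokine receptor Ccr2 (−1.39 ± 0.28) and the galectin Lgals3 (−1.43 ± 0.29). Of 20 Kupffer cell markers, 4 fell and 1 rose (5 and 1 adjusted over the list alone). The median was −0.45 (camera adjusted p = 0.0162, adjusted p = 0.54 with an estimated correlation), a call that ended without CCl4 4 (0.0625), CCl4 7 (0.0747) or CCl4_PTH 1 (0.0816). Of 31 T and NK markers, none passed in edgeR, where 11 had an unadjusted p under 0.05, all lower, and DESeq2 called 7 lower and voom 1 lower. The list had a median of −1.22 (camera adjusted p = 0.000723, adjusted p = 0.507 with an estimated correlation). Its score was 1.42 in CCl4 4 and 0.808 in CCl4 7. The other CCl4 libraries had −1.60 to −0.274 and the CCl4_PTH libraries −2.37 to −0.313, so the fall rested largely on CCl4 4 and CCl4 7. Of 19 neutrophil markers, Fpr2 fell, no member passed adjusted over the list alone, and the list did not pass. Its median was 0.10 (−0.06 with library sizes only), its mean −0.15 and its test downward (camera adjusted p = 0.0647). It passed without CCl4_PTH 1 (median −1.73, camera adjusted p = 9.43e-05), CCl4 1 (0.0323), CCl4 4 (0.0414), CCl4 5 (0.0203), CCl4 8 (0.00537) or CCl4_PTH 3 (0.0345). Of 35 cytokine and chemokine genes, Ccl22, Cxcl10, Icam1, Tnf and Vcam1 fell (2 higher and 12 lower adjusted over the list alone). The median was −0.77 (camera adjusted p = 6.76e-06, adjusted p = 0.318 with an estimated correlation). Of 33 interferon-stimulated genes, Gbp2, Lgals3bp, Oasl2 and Rsad2 fell (4 adjusted over the list alone). The median was −0.60 (camera adjusted p = 0.000241, adjusted p = 0.507 with an estimated correlation). The interferon score was 4.25 in both CCl4 4 and CCl4 7. The other CCl4 libraries had 2.57 to 3.47 and the CCl4_PTH libraries 2.07 to 3.27, so this fall too rested largely on CCl4 4 and CCl4 7. Of 24 acute phase genes, Saa4 rose (1 adjusted over the list alone). The list did not pass (median 0.50, camera adjusted p = 0.835). Without CCl4_PTH 1 its median was −0.51 and the list passed as lower (camera adjusted p = 0.00159).

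Of 30 immediate early genes, 12 fell with PTH (16 adjusted over the list alone). The median was −0.85 (camera adjusted p = 5.14e-09, adjusted p = 0.206 with an estimated correlation). Examples were Atf3 (−2.67 ± 0.38) and Ier5 (−0.95 ± 0.18). Of 28 stress response genes, 10 fell (10 adjusted over the list alone). The median was −0.30, which is −0.47 without CCl4_PTH 1 (camera adjusted p = 7.83e-06, adjusted p = 0.318 with an estimated correlation), and the chaperone Hspa5 fell by 1.01 ± 0.24 on the log2 scale. Of 22 p53 targets, 7 fell (1 higher and 9 lower adjusted over the list alone). The median was −0.54 (camera adjusted p = 1.52e-06, adjusted p = 0.13 with an estimated correlation). Of 26 NRF2 targets, 3 rose and 7 fell (4 and 7 adjusted over the list alone). The median was −0.37 (camera adjusted p = 0.00826, adjusted p = 0.257 with an estimated correlation), a call that ended without CCl4_PTH 1 (0.0766). Of 35 cell cycle genes, Mki67 fell, by 0.50 ± 0.16 on the log2 scale, from 18 ± 4.19 to 12.7 ± 1.99 CPM (SD, n = 6, edgeR adjusted p = 0.0472), no member passed adjusted over the list alone, and the list had a median of −0.32 (camera adjusted p = 0.00133, adjusted p = 0.291 with an estimated correlation). The Mki67 call ended in most alternatives, and with 1 library left out its adjusted p ran from 0.00757 without CCl4 5 to 0.116 without CCl4 4. Of 23 oncofetal genes, Akr1c18, Cd44, Golm1, Ly6d and Spink1 fell (7 adjusted over the list alone). The median was −0.41 (camera adjusted p = 8.28e-05, adjusted p = 0.13 with an estimated correlation). Afp (−0.06 ± 0.24, edgeR adjusted p = 0.916), Gpc3 (−0.40 ± 0.38, 0.558) and H19 (−1.39 ± 0.84, 0.304) did not pass.

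Of 25 collagen and matrix genes, Col4a2 fell with PTH, by 0.59 on the log2 scale (1 adjusted over the list alone), and 24 did not pass. The median was −0.24, which is −0.41 without CCl4_PTH 1 (camera adjusted p = 0.00188, adjusted p = 0.492 with an estimated correlation). Of 21 matrix remodelling genes, Mmp12, Mmp13, Mmp14 and Plau fell (6 adjusted over the list alone). The median was −0.42, which is −0.89 without CCl4_PTH 1 (camera adjusted p = 3.72e-06, adjusted p = 0.257 with an estimated correlation). Timp1 did not pass (−0.14 ± 0.75, edgeR adjusted p = 0.932), where CCl4_PTH 1 held 13.8 CPM and the value without it was −1.56 (edgeR adjusted p = 0.0716). Of 20 TGF-beta genes, Tgfb1 (−0.81 ± 0.20) and Tgfbi fell (2 adjusted over the list alone). The median was −0.26 (camera adjusted p = 0.00772, adjusted p = 0.291 with an estimated correlation). Of 22 stellate cell markers, Spon2 and Vim fell (2 adjusted over the list alone), and Acta2 did not pass (0.47 ± 0.53, edgeR adjusted p = 0.62). CCl4_PTH 1 held 10.6 CPM of Acta2, and without it the sign turned (−0.39, edgeR adjusted p = 0.563). The list did not pass (median −0.08, which is −0.26 without CCl4_PTH 1, camera adjusted p = 0.129). Of 19 cholangiocyte genes, none passed in edgeR, where 1 had an unadjusted p under 0.05, DESeq2 called none and voom 1, and the list did not pass (median −0.31, camera adjusted p = 0.0752), although it did without CCl4 5 (0.00543), CCl4_PTH 1 (0.0494), CCl4_PTH 3 (0.0286) or CCl4_PTH 8 (0.0149). Of 21 sinusoidal endothelial markers, 1 rose and 1 fell, and the list did not pass (median 0.04, which is −0.05 with library sizes only, camera adjusted p = 0.445). Of 21 capillarised endothelial markers, Vegfa rose and Vcam1 fell (1 and 2 adjusted over the list alone). As a list they did not pass (median −0.21, camera adjusted p = 0.0963).

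The naming rule also took genes with few counts or uncertain identity. With PTH, Hsd3b5 (5.41 ± 1.11, not passing in voom with quality weights, 0.248), Mup19 (4.40 ± 0.90), Mup-ps17 (4.77 ± 1.33), Cyp3a41b (5.02 ± 1.5) and Vmn1r90 (4.09 ± 0.63, overlapping another gene in sense) rose, where Cyp3a41b (edgeR adjusted p = 0.0487) and Mup-ps17 (0.0281) ended in several alternatives. CCl4_PTH 6 held 9.02 CPM of Hsd3b5, against 0.0426 to 1.42 in the rest of its group. CCl4_PTH 2 held 9.53 CPM of Cyp3a41b, against 0 to 2.63 in the rest. Over the CCl4_PTH libraries, Mup19 ran from 2.38 to 625 CPM and Mup-ps17 from 0 to 8.38 CPM. Sprr1a (−7.29 ± 1.18), Vmn2r3 (−5.82 ± 0.74), the T cell receptor gene Trdc (−3.95 ± 0.80, with an antisense gene over its exons), the secretory transcription factor Bhlha15 (−3.83 ± 0.51), Mmp13 (−3.18 ± 0.78) and Evi2b (−3.07 ± 0.55, overlapping another gene in sense) fell. Among long noncoding RNAs, Hectd2os (2.64 ± 0.78, edgeR adjusted p = 0.036, ending in several alternatives), Gm31583 (2.61 ± 0.54) and Gm15998 (2.05 ± 0.52, antisense to another gene) rose, and Gm17767 (−1.27 ± 0.33), Gm19705 (−1.19 ± 0.28) and AI506816 (−1.05 ± 0.21) fell.

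**Figure D2:**
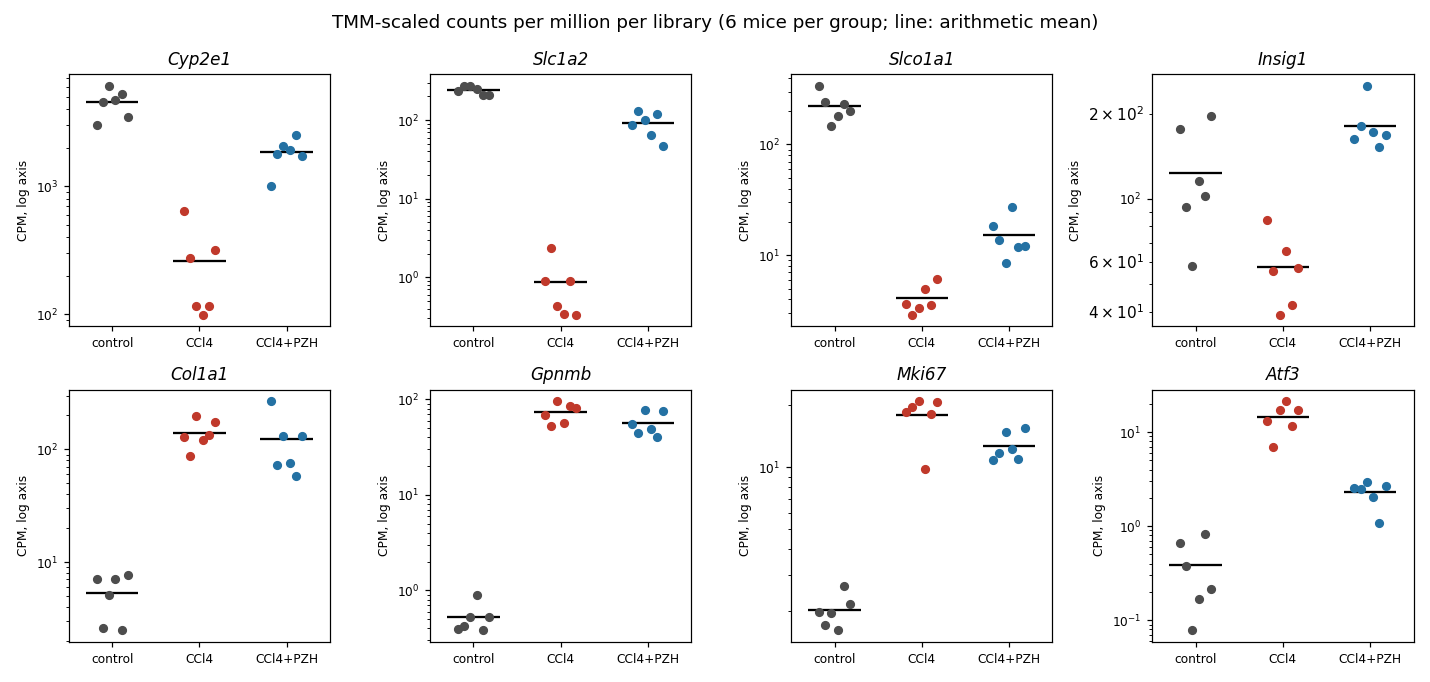
CPM of 8 genes in each library on log axes, by group, with a line at the mean of each group. Slc1a2 averages 242, 0.874 and 91.5 CPM and Atf3 averages 14.6 CPM in CCl4 and 2.29 CPM in CCl4_PTH libraries.

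**Figure D3:**
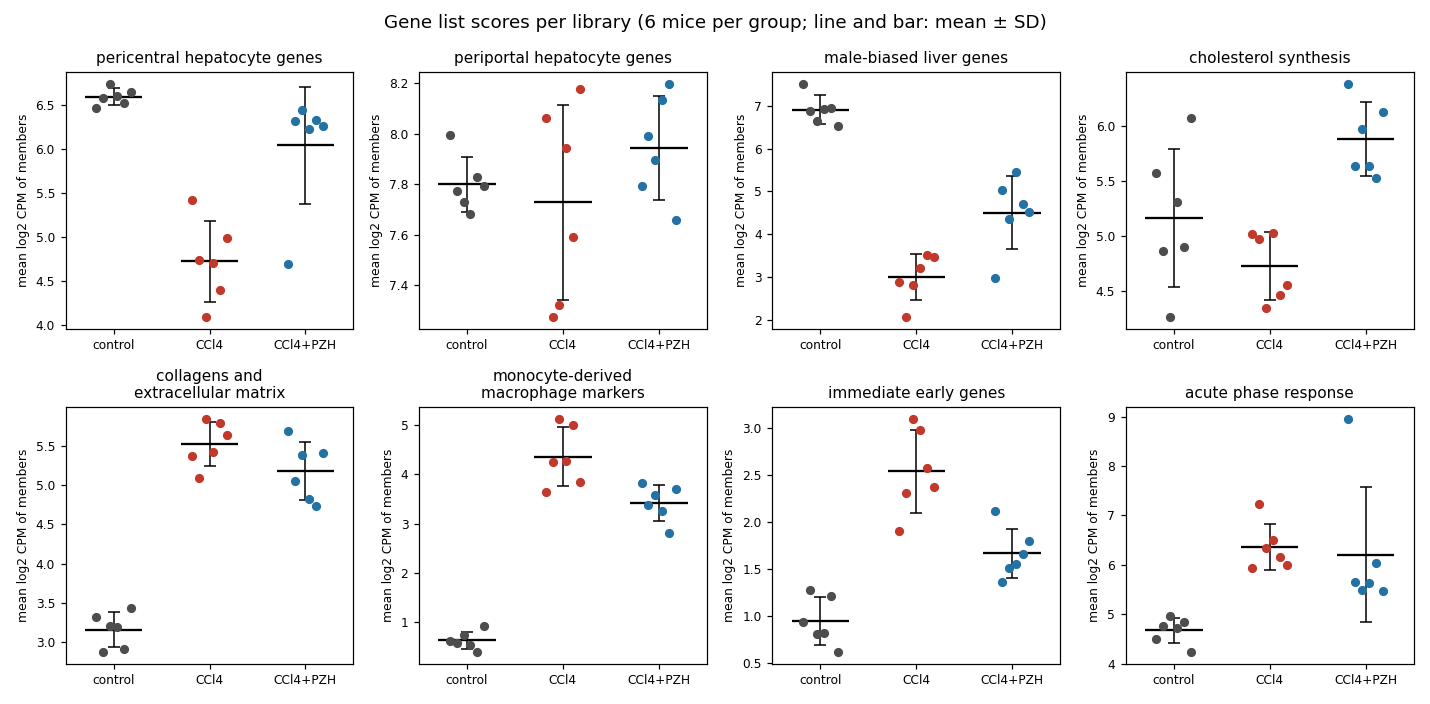
Scores of 8 gene lists in each library (mean log2 CPM of the members) by group, with bars for the mean and SD. In the acute phase panel CCl4_PTH 1 stands at 8.95, above the other 5 CCl4_PTH libraries at 5.46 to 6.03.

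In CCl4_PTH against CCl4, 1551 genes were higher and 1081 lower with PTH, 12.1% of those tested (edgeR quasi-likelihood, Benjamini-Hochberg), 361 and 330 of them beyond 2-fold, with 93 and 37 long noncoding RNAs. The counts moved by over 1.5 times without CCl4 4 (941 higher, 582 lower), CCl4 7 (1018 and 580), CCl4_PTH 3 (649 lower), CCl4_PTH 6 (622 lower) or CCl4_PTH 7 (934 and 575), and without CCl4_PTH 1 they were 2286 and 1568. With library sizes only, the higher share of calls went from 58.9% to 43.4% and the median of all genes from −0.03 to −0.13.

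The third comparison asked how far livers with CCl4 and PTH lay from control livers. Here 24 of 25 collagen genes, 22 of 24 macrophage markers and 26 of 35 cell cycle genes were higher than in control, and 30 of 34 fatty acid oxidation and 20 of 32 male-biased genes were lower. These 5 lists passed camera with its preset correlation and did not pass with an estimated one (adjusted p from 0.0838 to 0.192 with an estimated correlation). Col1a1 was 23.0-fold higher than in control (4.52 ± 0.42, edgeR adjusted p = 1.52e-06) and Mki67 6.32-fold higher (2.66 ± 0.17, edgeR adjusted p = 1.82e-08). Cyp2e1 was 2.47-fold lower (−1.30 ± 0.39, edgeR adjusted p = 0.0171), which did not pass with the ribosomal RNA share as a covariate (−0.98, 0.135) or with library sizes only (−0.79, 0.0699).

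With PTH, 24 of 25 collagen genes were higher than in control (24 adjusted over the list alone, median 2.09, camera adjusted p = 5.36e-21, adjusted p = 0.0838 with an estimated correlation), as were 17 of 21 matrix remodelling genes (17 adjusted over the list alone, median 1.65, camera adjusted p = 2.68e-07, adjusted p = 0.213 with an estimated correlation) and 26 of 35 cell cycle genes (27 adjusted over the list alone, median 1.85, camera adjusted p = 7.54e-13, adjusted p = 0.0838 with an estimated correlation). Of 24 macrophage markers 22 were higher (22 adjusted over the list alone, median 2.63, camera adjusted p = 4.43e-13, adjusted p = 0.139 with an estimated correlation), and of 19 neutrophil markers 17 (17 adjusted over the list alone, median 5.10, which is 3.12 without CCl4_PTH 1, camera adjusted p = 0.000426, adjusted p = 0.48 with an estimated correlation, 0.0608 with library sizes only). Of 31 T and NK cell markers 9 were higher (10 adjusted over the list alone, median 1.47, camera adjusted p = 0.00789, adjusted p = 0.608 with an estimated correlation, and 0.877 with library sizes only, where the test turned), and of 33 interferon-stimulated genes 13 (14 adjusted over the list alone, median 0.69, camera adjusted p = 0.000834, adjusted p = 0.548 with an estimated correlation). Of 34 fatty acid oxidation genes, 30 were lower and 1 higher (31 and 2 adjusted over the list alone, median −0.87, camera adjusted p = 6.13e-14, adjusted p = 0.192 with an estimated correlation). The score of control 1, 5.44, lay inside the 5.23 to 5.87 of the CCl4_PTH libraries, while the other controls had 6.42 to 7.22. Of 32 male-biased genes, 20 were lower (20 adjusted over the list alone, median −1.48, camera adjusted p = 8.34e-14, adjusted p = 0.139 with an estimated correlation), and of 30 pericentral genes 11 were lower and 3 higher (11 and 3 adjusted over the list alone, median −0.54, camera adjusted p = 0.000132, adjusted p = 0.47 with an estimated correlation). Of 25 cholesterol synthesis genes, 9 were higher than in control (13 adjusted over the list alone, median 0.72, camera adjusted p = 0.000426, adjusted p = 0.528 with an estimated correlation). Cholesterol scores ran from 4.26 to 6.07 in control libraries, with controls 1 and 8 highest, and from 5.53 to 6.39 in CCl4_PTH libraries, ranges that overlap.

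Timp1 (8.19 ± 1.29, 6.73 without CCl4_PTH 1, 4 counts in control), Gpc3 (2.45 ± 0.42), Afp (0.90 ± 0.24) and Tgfb1 (0.68 ± 0.20) were higher with CCl4 and PTH than in control, where Tgfb1 did not pass without CCl4_PTH 8 (0.54, 0.0562). H19 (1.74 ± 0.92, edgeR adjusted p = 0.172) did not pass, and passed without control 8 (3.15, 0.0256) and in voom with quality weights (0.0485). Acta2 (0.95 ± 0.54, edgeR adjusted p = 0.209) did not pass, and passed with library sizes only (0.0282), while without CCl4_PTH 1 its log2 fold change was 0.04 (edgeR adjusted p = 0.953). Cyp7a1 (0.84 ± 0.68, edgeR adjusted p = 0.384) and Alb (−0.46 ± 0.25, 0.188) did not pass, and Alb passed with only the 2 groups compared (0.0495). Sult1e1, an estrogen sulfotransferase, and the neutrophil genes Mmp8 and Cd177 had 0 counts in control and were at least 806-fold, 425-fold and 376-fold higher, mostly through CCl4_PTH 1, which held 33.9, 16.9 and 14.8 CPM. The other CCl4_PTH libraries held 0 to 1.47, 0.126 to 0.755 and 0.195 to 0.910 CPM, so the bounds would be lower without CCl4_PTH 1. The fitted log2 fold changes were 12.07, 11.16 and 10.99, and 8.23, 8.30 and 8.31 without CCl4_PTH 1. With 0 counts in control, the size of these fitted values is not fixed by the data. The Sult1e1 call ended in voom with quality weights (0.208) and with the ribosomal RNA share as a covariate (0.130). Mup-ps16 (−8.46 ± 0.66, overlapping another gene in sense), Fitm1 (−7.09 ± 1.13, with an antisense gene over its exons) and Mup17 (−6.74 ± 1.17) were the genes the rule took among those lower.

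In CCl4_PTH against control, 3798 genes were higher and 2253 lower, 27.7% of those tested (edgeR quasi-likelihood, Benjamini-Hochberg), 2502 and 590 of them beyond 2-fold, with 264 and 128 long noncoding RNAs. With library sizes only, the higher share of calls went from 62.8% to 96.4% and the median of all genes from 0.04 to 0.51.

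Whether PTH moved genes back towards control was asked of the 10362 genes called in CCl4 against control. Of these, 9340 (90.1%) had the opposite sign in CCl4_PTH against CCl4, 2381 were called there with the opposite sign, and 10 were called with the same sign, where 612 and 636 would fall together if the calls were independent. Of 5735 genes that rose with CCl4, 952 (16.6%) fell with PTH, and of 4627 genes that fell with CCl4, 1429 (30.9%) rose with PTH. The slope across the called genes was −0.28, and the correlation across all 21840 genes, which are not independent replicates, was −0.63.

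Because both comparisons share the CCl4 libraries, part of this opposition arises with no treatment effect. In simulated data with the CCl4 effect kept and PTH without effect, 56.9% of called genes had the opposite sign. The slope was −0.04 and the correlation across all genes −0.14, and with all groups unchanged the correlation was −0.49. There 0 genes were called in CCl4_PTH against CCl4 at all (edgeR quasi-likelihood). The 0 opposite calls follow from that and are no measure for the 2381. The simulated genes were drawn independently, so variation that many genes of a library share is left out. The covariance of the fold changes over all genes was −0.551 against −0.0842 in the simulated data, a difference of −0.466. With 3 CCl4 libraries used in each comparison, 85.6% of called genes had the opposite sign and 992 were called with it (mean of 20 splits, from 109 to 3086), the slope was −0.25 and the covariance −0.483. The 2381 genes became 1374 without CCl4 4, 1439 without CCl4 7, 1570 without CCl4_PTH 6 and 1385 without CCl4_PTH 7.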

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

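The position of CCl4_PTH 1, the splits of the CCl4 libraries and the other splits of the samples were set before their results were seen, and the remaining tests here (the ribosomal RNA covariate, genes beyond the CCl4 libraries, acute phase, cholesterol and scaling of CCl4_PTH 1, both hepatocyte share tests, the Mup test and the sex gene test) were chosen only after the result was seen. Each library value below lay far from the other 5 of its group, by the ratio of its gap to the range. Such a gap was found in 45 of 387 groups tested (11.6%), and 19 of the 45 were in CCl4_PTH 1, 5 in control 1 and 4 in CCl4 5. Chance flags about 1 in 20 groups of normal values, but many values were CPM, where 5 zeros and 1 other value are always flagged. Sult1e1, Mmp8 and Cd177 were also named for a rise that came mostly through CCl4_PTH 1. The share of 11.6% therefore cannot be set against 1 in 20.

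CCl4_PTH 1 stood apart from its group in hepatocyte, acute phase and neutrophil genes. By the test set beforehand it fits a CCl4 library with a wrong label: over the genes called without it, its position between the CCl4 mean (0) and the CCl4_PTH mean (1) was 0.135, inside the CCl4 range of −0.237 to 0.519 and outside the 0.847 to 1.19 of the other CCl4_PTH libraries. The position alone cannot tell a wrong label from a treated liver that lay close to the CCl4 group over those genes. Against a wrong label, 0.826% of genes chosen without it lay over 2 (log2) beyond every CCl4 library on the CCl4_PTH side, against 0.0512% to 0.286% for CCl4 libraries placed the same way (SD 0.0968), its cholesterol synthesis score exceeded the highest CCl4 library by 1.36 (SD of the CCl4 libraries 0.310), and it held 86.8 CPM of Slc1a2 (CCl4 0.333 to 2.36) and 2.55 CPM of Atf3 (CCl4 6.99 to 21.3), genes named with it in the fit. A wrong scale would move all genes alike, but the pericentral difference lay at −1.65 relative to the median gene. The pericentral score is itself one of the values that flagged the library, so this is not independent evidence. An admixture of CCl4 RNA cannot be told apart, since the acute phase score, 1.72 above the highest of the other 11 libraries, is another of the values that flagged the library. A wrong label thus accounts for the position but not for these genes, and the verdict on the position, for a time overruled by the cholesterol test, follows the test set beforehand.

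Of 30 pericentral genes, 23 fell with CCl4 and 16 rose with PTH (adjusted p = 0.196 and 0.206 with an estimated correlation). A lower share of hepatocytes would lower periportal genes alike, but the pericentral minus periportal score was lower in CCl4 than in control by −1.80 (exact permutation p = 0.00216, Benjamini-Hochberg adjusted p = 0.00433 over 6 tests) and differed by 1.11 between CCl4_PTH and CCl4 (exact permutation p = 0.00649, adjusted p = 0.00779). With the ribosomal RNA share as a covariate, the median rise with PTH was 1.23 against 1.14 without it. With different CCl4 libraries in each comparison, the lowest median rise over 20 splits was 0.619. A response of pericentral hepatocytes to CCl4 and PTH may account for it, as a hypothesis found and tested on the same data, while a loss of those cells and a change of expression within them were not told apart by any test here.

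Of 32 male-biased genes, 29 fell with CCl4 (adjusted p = 0.124 with an estimated correlation). Reads shared between Mup paralogs would leave the other members in place, but the median over members that are not Mup genes was −3.08, with 22 of 24 lower. Libraries from female mice would show it, but Ddx3y was above Xist in 18 libraries. A lower share of hepatocytes would lower secreted protein genes alike, but the male-biased minus secreted protein score differed by −3.45 between CCl4 and control (exact permutation p = 0.00216, adjusted p = 0.00433 over 6 tests). Between CCl4_PTH and CCl4 this score differed by 1.11, which did not pass (exact permutation p = 0.0519, adjusted p = 0.0519). CCl4_PTH 1 scored 2.99 for male-biased and 10.4 for secreted protein genes. The other CCl4_PTH libraries scored 4.36 to 5.46 and 9.46 to 9.90, and the difference without CCl4_PTH 1 was not tested. A response of sex-biased liver expression to CCl4 may account for the fall of male-biased genes, as a hypothesis, and hormones were not measured in the data used here.

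Other splits of the libraries did not reach the number of genes called. Of 100 splits of the 12 libraries, the real one included, 1 called as many in CCl4 against control (10362, highest other 5714). It was also 1 in CCl4_PTH against CCl4 (2632, highest other 35) and in CCl4_PTH against control (6051, highest other 3048). No share below 1 in 100 could be reached. Splits that mix the groups put the group difference into the spread, and a technical difference that follows the groups would give the same result.

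The other values of CCl4_PTH 1 far from its group were −43.4 on the second principal component, scores of 4.52 for P450 genes, 5.42 for bile acid synthesis, 8.95 for acute phase, 4.69 for pericentral, 3.59 for neutrophil, −2.40 for pancreatic acinar and 0.0398 for adipocyte genes, and CPM of 19.5 for Mmp7, 13.8 for Timp1, 15.4 for AI506816, 8.68 for Gm12840, 268 for Col1a1, 10.6 for Acta2, 0.272 for Vmn1r90, 6700.1 for Serpina3k, 33.9 for Sult1e1, 16.9 for Mmp8 and 14.8 for Cd177. Control 1 had scores of 2.81 for pancreatic acinar and 7.43 for mitochondrially encoded genes, and CPM of 0.0463 for Timp1, 0.116 for Vmn2r3 and 0.440 for Mmp13. Control 4 had 0.888 CPM for Gpnmb, control 5 had a cytokine score of −0.644 and 0.0611 CPM for Mmp7, and control 8 had 0.492 CPM for H19. CCl4 1 had a mesothelial score of 1.54, CCl4 2 had CPM of 2.36 for Slc1a2, 5.11 for Cd177 and 2.76 for Fitm1, CCl4 5 had CPM of 6.59 for Inava, 9.76 for Mki67, 0.484 for Mup-ps17 and 2.83 for Gm15998, and CCl4 7 had 0.0369 CPM for Cfd. CCl4_PTH 2 had CPM of 0.0603 for Mup-ps16, 269 for Mup12 and 9.53 for Cyp3a41b, CCl4_PTH 3 had 251 CPM for Insig1, CCl4_PTH 6 had CPM of 9.02 for Hsd3b5 and 0.234 for Gm13775, and CCl4_PTH 8 had CPM of 0.221 for Sprr1a and 2.78 for Gm36161.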

How the results depend on the processing

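The tests with the ribosomal RNA loci removed, with the ribosomal RNA share as a covariate, with library sizes only, with upper quartile scaling for the lists and without control 1 and CCl4_PTH 1 were chosen only after the result was seen. The lists were tested under 26 alternatives, among them fry and the estimated correlation, and were not run in DESeq2, in voom, without the filter, with only the 2 groups compared or with the ribosomal RNA covariate. Of their values, 155 lost the call, 27 gained one, 5 reversed and 3167 kept their side of the threshold, with the direction of the test kept wherever either was called. The sign of the list median turned in 68 values, 15 of them with library sizes only. Under 29 alternatives, 3059 values of named genes kept their side of the threshold (19 of them turned sign, never past it), 91 lost the call and 8 gained one. Under 31 alternatives, 171 counts stayed within 1.5 times and 39 did not. The estimated correlation accounted for 92 of the lost list calls. With a change beyond 2-fold, by construction a stricter test, the counts higher and lower were 3797 and 1418 (CCl4 against control), 361 and 330 (CCl4_PTH against CCl4) and 2502 and 590 (CCl4_PTH against control). With library sizes only they were 11275 and 1061, 476 and 621, and 9559 and 353. Of the genes called in CCl4 against control and in CCl4_PTH against control, 1646 and 890 turned sign, counted whether or not they passed again. Genes lower in CCl4_PTH against CCl4 numbered 1798 in DESeq2, 1969 in voom with quality weights, 709 with only the 2 groups compared (fewer samples) and 1916 without control 1 and CCl4_PTH 1. With the ribosomal RNA share as a covariate, 2512 genes were higher and 987 lower in CCl4_PTH against control. With the label numbers as a block, 42 and 42 genes were called in CCl4_PTH against CCl4 and 2501 and 842 in CCl4_PTH against control, but the numbers do not pair the mice: 0 pairs with a shared number correlated above 0.1, and 0 libraries correlated best with their own number. Genes called with opposite signs, 2381 in the report, numbered 3610 in voom with quality weights, 1556 with only the 2 groups compared, 81 with the block, 972 with library sizes only and 992 with the CCl4 libraries parted. With 1 library left out, genes in CCl4_PTH against CCl4 ran from 934 (without CCl4_PTH 7) to 2286 (without CCl4_PTH 1) higher and from 575 to 1568 lower without the same libraries, and opposite calls ran from 1374 without CCl4 4 to 3413 without CCl4_PTH 1. The acute phase list in CCl4_PTH against CCl4 ran from −0.51 without CCl4_PTH 1 to 0.68 without CCl4 5, and was −0.53 without control 1 and CCl4_PTH 1. With library sizes only, the test turned in CCl4_PTH against control for female-biased genes (median 0.75), T and NK markers (2.02) and ribosomal proteins (0.42). Except where noted, the cause was not tested. Depth and 6 mice per group left many changes below 2-fold undetected in simulated data.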

Other observations

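The tests with library sizes only were chosen only after the result was seen, as were the members named. Circadian clock genes changed with CCl4: of 20, 14 fell and 2 rose (15 and 2 adjusted over the list alone), with a median of −1.05 (camera adjusted p = 8.45e-05, adjusted p = 0.124 with an estimated correlation), where the activators Arntl (2.03 ± 0.40, log2 fold change ± SE, n = 6 per group) and Npas2 (2.49 ± 0.55) rose and Dbp (−1.88 ± 0.43) and Nr1d1 (−1.48 ± 0.25) fell. With PTH against CCl4, 7 rose (13 higher and 1 lower adjusted over the list alone), with a median of 0.61 (camera adjusted p = 0.000419, adjusted p = 0.206 with an estimated correlation), among them Dbp (1.43 ± 0.42) and Per3 (1.23 ± 0.35). The hour of tissue collection is not given in the sources used here.

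Of 25 B and plasma cell markers, 22 rose with CCl4 (22 adjusted over the list alone), with a median of 1.78 (camera adjusted p = 0.000273, adjusted p = 0.257 with an estimated correlation). With PTH against CCl4, the immunoglobulin genes Ighg1 (2.40 ± 0.65) and Iglc1 (1.51 ± 0.41) rose while the B cell receptor gene Cd22 (−1.14 ± 0.36) and Derl3 (−2.08 ± 0.44) fell (2 higher and 3 lower adjusted over the list alone), and the list did not pass (median −0.30, which is −0.18 without CCl4_PTH 1, camera adjusted p = 0.765). Of 43 long noncoding RNAs studied in liver or cancer, 17 rose and 8 fell with CCl4 (17 and 8 adjusted over the list alone), and the list did not pass (median 0.23, camera adjusted p = 0.291). With PTH against CCl4, 5 rose and 7 fell (6 and 10 adjusted over the list alone), without a call for the list (median −0.25, camera adjusted p = 0.13), where the imprinted Rian rose (2.02 ± 0.54) and the snoRNA hosts Gas5 (−0.53 ± 0.10), Snhg1 (−0.59 ± 0.14) and Zfas1 (−0.61 ± 0.14) fell.

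Markers of other tissues were measured beside these groups. Of 16 mesothelial markers, 12 rose and 1 fell with CCl4 (12 and 1 adjusted over the list alone, median 1.34, camera adjusted p = 0.00655, adjusted p = 0.408 with an estimated correlation), and with PTH against CCl4 Krt8 and Krt18 fell (median 0.04, which is −0.10 with library sizes only and 0.13 without CCl4_PTH 1, camera adjusted p = 0.31). Of 11 smooth muscle and gallbladder markers, 7 rose with CCl4 (7 adjusted over the list alone, median 1.34, camera adjusted p = 0.0133, adjusted p = 0.163 with an estimated correlation, 0.108 with library sizes only). Of 11 adipocyte markers, 2 rose and 6 fell with CCl4 (2 and 6 adjusted over the list alone, median −0.58, which is −0.04 with library sizes only, camera adjusted p = 0.249, and 0.00445 with library sizes only). Of 5 skeletal muscle markers, Casq1 rose with CCl4 (1 adjusted over the list alone, median 0.50, camera adjusted p = 0.552). The 3 measured pancreatic acinar markers, Cela1, Cela2a and Ctrl, fell with CCl4 (3 adjusted over the list alone, median −1.78, too few for camera), where control 1 had a score of 2.81 against −1.26 to 0.0431 in the other 5 controls. Of 16 erythroid and blood markers, 4 rose and 3 fell with CCl4 (4 and 3 adjusted over the list alone, median 0.29, camera adjusted p = 0.561), and with PTH against CCl4 Slc4a1 fell (1 higher and 2 lower adjusted over the list alone, median −0.49, camera adjusted p = 0.0474, adjusted p = 0.257 with an estimated correlation, ending in 6 of the fits with 1 library left out, at 0.0503 to 0.0800, and with relative log expression size factors at 0.0557). Of 25 iron and heme genes, 4 rose and 9 fell with CCl4 (4 and 9 adjusted over the list alone, median −0.04, which is 0.52 with library sizes only, camera adjusted p = 0.161).

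Of 13 mitochondrially encoded genes, 12 fell with CCl4 (13 adjusted over the list alone, median −0.67, camera adjusted p = 0.000169, adjusted p = 0.408 with an estimated correlation). As a share of all counts, without composition factors, mitochondrial messenger RNA was 1.11% ± 0.114 in control and 1.04% ± 0.212 in CCl4 libraries (SD, n = 6). The size of this fall therefore depended on the scaling. With PTH against CCl4, mt-Co3 (0.46 ± 0.15) and mt-Nd3 (0.48 ± 0.15) rose (2 adjusted over the list alone, median 0.29, camera adjusted p = 0.00719, adjusted p = 0.507 with an estimated correlation). Of 38 cytosolic ribosomal protein genes, 7 rose with CCl4 (2 adjusted over the list alone, median 0.11, camera adjusted p = 0.138, and 9.16e-06 with library sizes only), and with PTH against CCl4 Rpl19 and Rps27a fell (none adjusted over the list alone, median −0.18, camera adjusted p = 6.76e-06, adjusted p = 0.318 with an estimated correlation).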
